A study of Mus musculus with 3 samples.

How the data were processed

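RNA from cultured mouse leukaemia cells was amplified to amino-allyl antisense RNA, coupled to Cy5 and hybridised to 1-colour arrays, per the labels' protocols. Groups and replicate numbers were taken from the sample titles: 2 sensitive arrays, replicates 1 and 2, and 1 resistant array. The authors deposited 1 table with an intensity per probe and array. Its values are linear and reach below 0, so the authors had subtracted a background. On each array 99.4% or more of the values were whole multiples of 1 step (1.24, 1.32 and 1.56 units, within 0.02 steps), as 1 factor per array gives. What the factors were set to, the scanner and the image software are not given in the sources used here. The sorted columns differed, so the arrays had not been quantile normalized. Of 26423 probes, 52.4%, 55.8% and 43.0% read at least 50 units on the arrays in the order given, and 2 on each array reached 65000 steps, close to the limit of a 16-bit scanner. No flags for background or saturation were used here.

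Probes were named through a table of the platform's gene symbols. Of the probes, 20377 had 1 symbol, 0 had several and 6046 had none. Of the symbols, 18210 matched a current mouse gene of the GRCm38.p6 annotation, 2126 an older name and 41 none. The build behind the array's design is not given in the sources used here, so the annotation served only for names and for which genes share a chromosome. The probe with the highest mean over the 3 arrays stood for each gene; 2278 of 17742 genes had more than 1 probe. No gene was named from a probe without a symbol.

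The design, the gene lists, the naming rule and most alternatives were fixed before the data were examined. The design had assumed log2 values or a plain log2 transform. The table held intensities with values below 0, so log2(intensity + 50) was used, and the offset of 50 was chosen after the data were examined. Differences on this scale understate the change of dim genes. The values were otherwise kept as deposited. limma 3.58.1 in R 4.3.3 was fitted to the 3 arrays (lmFit, then eBayes with a variance trend), with resistant minus sensitive as the contrast. There was 1 residual degree of freedom per gene, from the sensitive arrays, and a prior of 11.2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes and a log2 difference of at least 1 in the same direction from each sensitive array. All 4205 genes of that size also passed the adjusted p. Error is given as the SD of 2 sensitive arrays or the SE of limma's difference.

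For 28 gene lists with 502 measured members, the median log2 difference was set against 10000 random lists of the same size matched on mean expression in 20 bins; this describes these arrays and is not a test between conditions. Each list was also counted with the adjustment made over the list alone. Since every gene of the size asked already passed the adjusted p, those counts could not differ from the calls as deposited, both directions together. The lists were tested with limma's camera as well, with a preset correlation of 0.01 and an estimated one. The estimate rested on 1 residual degree of freedom, so its p cannot count for or against a list. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the rest.

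Genes were named by rule: Dck in every case; the 15 called genes with the largest rise and the 15 with the largest fall, ranked by the smaller of the differences from the sensitive arrays, among genes whose higher group mean reached the median of all genes and whose symbol was not a clone, accession, predicted gene or olfactory or vomeronasal receptor name; and from each list the called members, at most 4 by size, with up to 2 well-known members that were not called. Intensity alone marked probes near 0 (at most 10 units). Counts of probes near 0 on the resistant array alone took only those of at least 500 units on both sensitive arrays.

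The limma step was tested on data simulated from the real arrays (17742 genes, 20 simulations, 200 genes changed in each). It recovered 99.5% of genes changed by 2 log2 units and 92.2% of those changed by 1.5, with 2.75 unchanged genes called on average. Every simulated array shared the sensitive levels and the fitted spread, without the dimness of the real resistant array, and genes were drawn independently. These figures therefore do not give the errors among the 4205 calls. In the list step, 5 of 100 simulated unchanged lists of 20 genes and 100 of 100 lists shifted by 1 log2 unit fell outside their random range.

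Alternatives were quantile normalization, centring on each array's median, leaving out the dimmest 25% of genes or those below the median, the mean of a gene's probes, eBayes without a trend or with a robust trend, other thresholds (adjusted p under 0.1 or alone, log2 differences of 0.6 and 2), and leaving out each sensitive array. Scaling on bright probes, offsets of 16 and 100, a floor of 50 in place of the offset, and leaving out probes near 0 on the resistant array alone were added after the data were examined. The comparison of a gene's further probes with its call, against 10000 random pairings of calls and probes on both scales, was also added then, as were the count of genes around Dck and the scan of near-zero probes in windows of 50 bright probes.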

Results

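The arrays measured messenger RNA in mouse myeloid leukaemia cells of the BXH-2 strain. Cytarabine (Ara-C) is a deoxycytidine analogue that stops DNA synthesis once the cell has phosphorylated it. The sensitive group held 2 arrays of the parental line B117P. The resistant group held 1 array of B117HS, a line raised from B117P under rising doses of cytarabine over about 10 weeks, whose IC50 for the drug was about 10 times that of its parent per the labels. The comparison asks which transcripts differ between the resistant line and its parent. Each array gave an intensity for 26423 probes, which named 17742 genes. Median intensity was 58.4 and 72.5 on the sensitive arrays and 24.9 on the resistant array. Nothing in the labels says that the sensitive arrays came from separate cultures, so p-values measure only the spread between these arrays, which may be technical, and the lone resistant array was assumed to vary like them. The small number of arrays limits the precision.

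The resistant cells carried far more Csn2, Igfbp7, Elane, Fcgr3, Bcl2 and Vegfa transcript than their parent, and far less Csf1r, Irf8, Psmb8, Psmb9, Ccnd1 and Ezh2. Among called genes of interferon response, antigen presentation and the monocyte lineage, more fell than rose. Dck, which encodes the kinase that first phosphorylates cytarabine, was not among the called genes. In limma, 4205 of 17742 genes were called at a Benjamini-Hochberg adjusted p under 0.05 with a log2 difference of at least 1 from each sensitive array. Of these, 926 were higher and 3279 lower in the resistant cells. The same size was reached between the 2 sensitive arrays by 152 genes.

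The resistant array was dimmer throughout, with a median log2 ratio of -0.76 to the mean of the sensitive arrays over 6167 probes of at least 500 units. After each array was scaled to remove that shift, 1737 genes were higher and 1512 lower. The share of higher genes among those called was 22.02% as deposited, 53.5% after this scaling, 52.7% after quantile normalization and 57.2% after centring on the medians. Calls held in the same direction as deposited and after scaling on bright probes for 923 higher and 1494 lower genes. Below, "rose" and "fell" are used of genes called on both scales unless the text says that a call held as deposited only, and log2 differences are those as deposited, to which the scaling adds at most 0.76. The 21 named genes called as deposited only were still below the sensitive mean after scaling, by log2 differences of -1.99 (Flt3) to -0.48 (Gart), and 2 of them, Flt3 and Prg2, still passed the size rule.

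**Figure D1:**
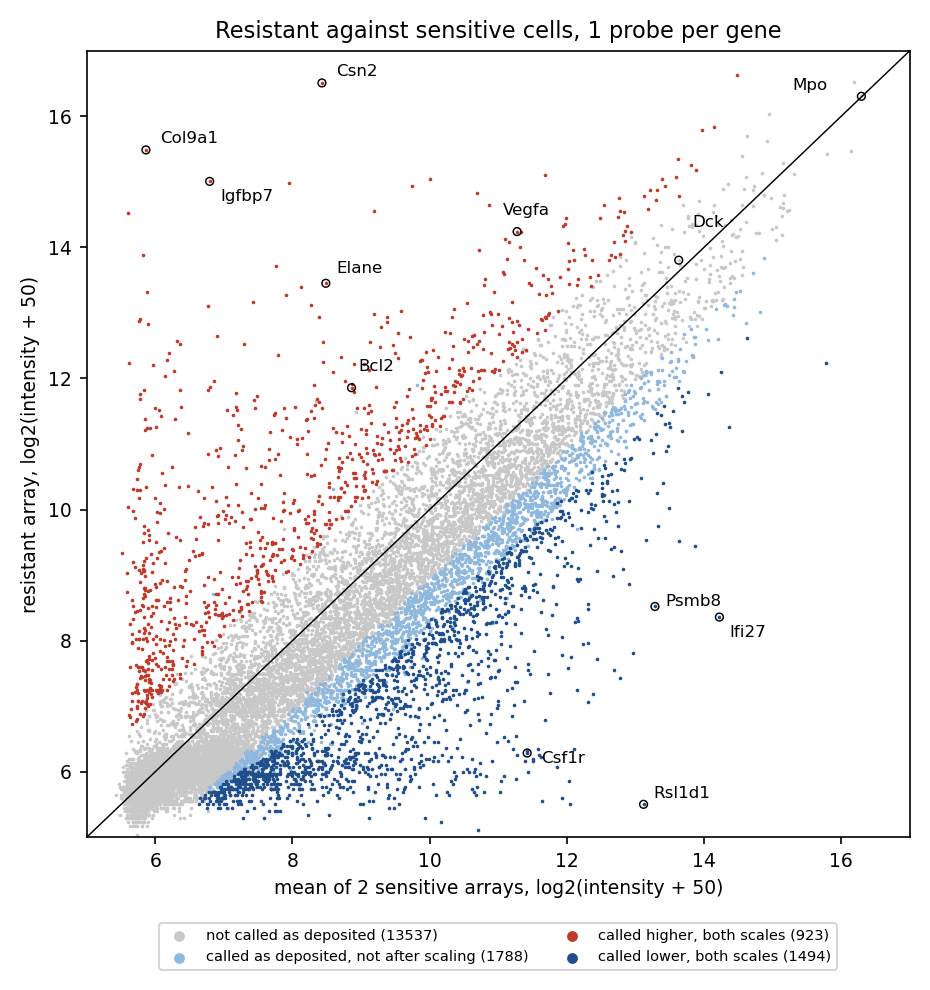
Each point is 1 gene, with the mean of the 2 sensitive arrays on the x axis and the resistant array on the y axis, both as log2(intensity + 50). Red points (923 genes) and dark blue points (1494 genes) were called on both scales, the line marks equal values, and Dck lies close to it while Csn2 and Psmb8 lie far from it.

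Most of the 15 largest rises began below 100 units on both sensitive arrays, and those of Csn2 and Igll1 began higher. Col9a1, Ppib, Pmp22, Serpine2, G0s2, Jaml and Sco2 were at or below 10 on both, where failed spots were not excluded. Col9a1, a chain of cartilage collagen IX, read 8.27 ± 2.36 (SD, n = 2) in sensitive cells and 45870 in resistant cells (log2 difference 9.62, SE 0.24, limma adjusted p = 4.66e-10). Csn2, the milk protein beta-casein, rose from 297 ± 48.7 to 93214, a log2 difference of 8.08. The secreted binding protein gene Igfbp7 went from 61.9 ± 20.7 to 32888 on its brighter probe, while its other probe read -3.73, 5.28 and 23.3. The protease inhibitor gene Serpine2 went from 8.97 ± 0.38 to 10208, and the myelin protein gene Pmp22 from 6.33 ± 3.35 to 15095. Igll1, part of the surrogate light chain of the pre-B cell receptor, rose by 7.04 on the log2 scale, from 194 and 199 to 32384. Ppib, a widely expressed cyclophilin, read -1.28 ± 0.05 on the sensitive arrays and 23528 on the resistant array. Also called higher were G0s2 (log2 difference 7.13), Jaml (7.12), St8sia5 (6.93), Sco2 (6.62), Hadh (6.34), Slc16a3 (6.25), Lcn2 (6.24) and Vat1l (6.18).

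Among the 15 largest falls, 8 were of genes whose probe read above 10 on the resistant array, from 17.1 for Pou2f2 to 278 for Ifi27, where the median of all probes was 24.9. Ifi27, an interferon-induced gene, fell from 19266 ± 3537 (SD, n = 2) to 278 (log2 difference -5.87, SE 0.22, limma adjusted p = 4.62e-09). The B-lineage transcription factor genes Pou2f2 and Bcl11a fell by 5.78 and 5.40, and the macrophage perforin gene Mpeg1 fell by 5.76. Scin, an actin-severing protein gene, fell by 5.34, the prostaglandin-degrading enzyme gene Hpgd fell by 5.35 and Ms4a6c fell by 5.20. Psmb9, an immunoproteasome subunit gene, went from 5026 ± 67.9 to 84.0. The other 7, Rsl1d1, Hax1, Tmem223, Nsmce4a, Get3, H1f1 and Gimap6, read between -4.67 and 9.33 on the resistant array. Rsl1d1, a nucleolar protein gene, read 8872 ± 981 in sensitive cells. Over all probes of at least 500 on both sensitive arrays, 47 of 6019 were at or below 10 on the resistant array, and these lay beside each other in the order of probe numbers more often than in 10000 permutations (7 neighbouring pairs against a mean of 0.358, p = 0.0001, the smallest these permutations can give). Tmem223, Nsmce4a, Get3 and Gimap6 were in such pairs. The layout of the spots was not used here, so neighbours by number need not lie together on the slide.

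Dck and the transporter gene Slc29a1 were not called, and 2 nucleotidase genes moved in opposite directions. The single Dck probe read 12919 and 12378 in sensitive cells and 14263 in resistant cells, a log2 difference of 0.17 (SE 0.20, limma adjusted p = 0.50). After scaling on bright probes the Dck difference was 0.93 with an adjusted p of 0.027, short of the size asked. Slc29a1, the main nucleoside transporter, differed by 0.17 (adjusted p = 0.53). Nt5e, the surface 5'-nucleotidase CD73, rose from 1744 ± 848 to 15968, a log2 difference of 3.24. Nt5c, a cytosolic nucleotidase, fell from 678 ± 24.7 to 42.0, a log2 difference of -2.98. Samhd1, which hydrolyses the active triphosphate, was called lower as deposited only (-1.54, and -0.81 after scaling). Cda, the deaminase that inactivates the drug, differed by 0.75 without a call as deposited and was called higher after scaling (1.39). Of 19 measured genes of cytarabine uptake, activation and inactivation, 1 was called higher and 2 lower as deposited, and 3 when adjusted over the list alone. After scaling on bright probes 5 were called higher and 1 lower. Here and below, counts adjusted over a list alone take both directions and equal the number called as deposited. This list's median of -0.04 lay above the central 95% of 10000 expression-matched random lists (-1.10 to -0.09), and camera gave it an adjusted p = 0.94 with an estimated correlation. No list had a smaller one, and 1 residual degree of freedom cannot fix that correlation. The camera p of this and later lists therefore cannot count for or against a shift. The call of Nt5e was lost on the adjusted p after quantile normalization and with a floor of 50 in place of the offset, where the log2 difference of Nt5e was 3.46 and 3.29.

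Nucleotide synthesis, the neighbourhood of Dck and the drug pumps showed no common shift. In the pyrimidine and deoxynucleotide synthesis list, 5 of 14 genes were called lower as deposited and 5 when adjusted over the list alone. Shmt1, a folate enzyme gene, fell by 1.81 on the log2 scale, while Mthfd1 (-1.38), Mthfd2 (-1.36) and Gart (-1.23) were called lower as deposited only. Rrm2, the small subunit of ribonucleotide reductase, differed by 0.34 as deposited and by 1.10 after scaling, where it was called higher. Among 9 genes near Dck on its chromosome, 1 was called, Utp3 (-1.58, as deposited only), and 1 when adjusted over the list alone. Among all 30 measured genes as near to Dck as the farthest of these, counted after the values were seen, Csn2 and Csn1s2a, both casein genes, were also called, higher on both scales, Csn1s2a on a probe near 0 on both sensitive arrays. For drug efflux transporters, 2 of 14 rose and 3 fell, 5 also when adjusted over the list alone. Abcb1b, which encodes a P-glycoprotein, fell from 833 ± 82.4 to 12.4 (log2 difference -3.82), and its neighbour Abcb4 from 808 ± 221 to 10.9. Abcc2 fell by 1.59, Abca3 rose by 1.52, and the pump gene Abcc1 differed by -0.58 as deposited and by 0.16 after scaling. The medians of these 3 lists lay inside the range of their random lists, at percentiles 27.2, 52.1 and 56.7. The call of Abcc2 was lost after quantile normalization (-0.96) and after centring.

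**Figure D2:**
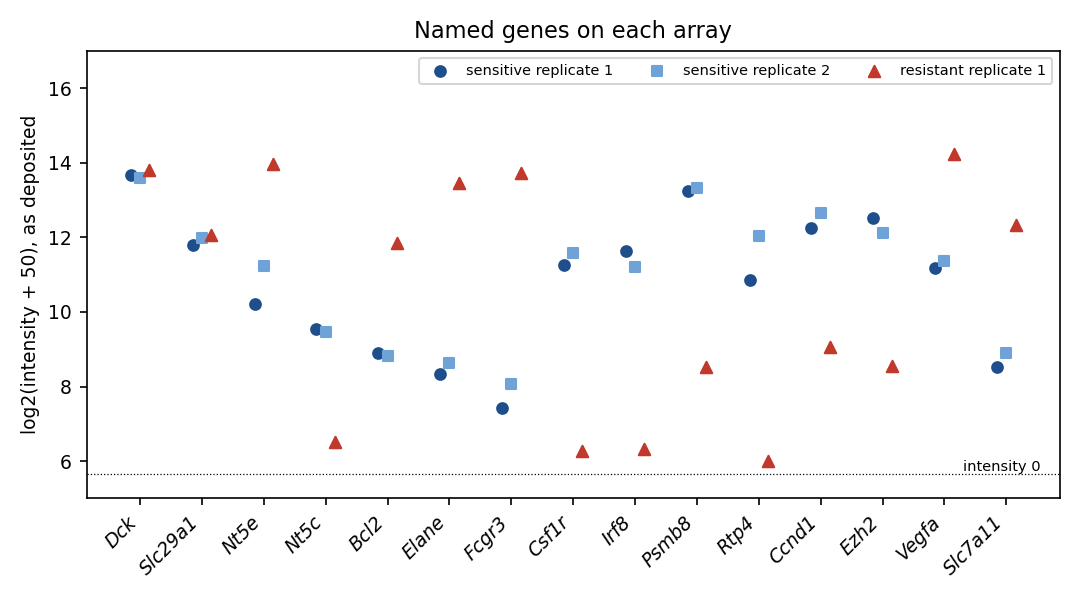
Points give log2(intensity + 50) as deposited for 15 genes on the 2 sensitive arrays (circles and squares) and the resistant array (triangles), and the dotted line marks an intensity of 0. Dck read 12919, 12378 and 14263, while Nt5e, Bcl2, Elane and Fcgr3 were higher and Csf1r, Irf8 and Rtp4 close to the dotted line on the resistant array.

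Most called monocyte genes fell, while several granule genes rose. Csf1r, the receptor for the main macrophage growth factor, fell from 2711 ± 421 (SD, n = 2) to 28.0 (log2 difference -5.14, SE 0.24, limma adjusted p = 1.60e-08). Irf8, a transcription factor of monocyte and dendritic cell fate, fell by 5.10, and the chemokine receptor gene Cx3cr1 fell by 4.89. Fcgr3, a low-affinity IgG receptor gene, moved the other way, from 172 ± 68.8 to 13474, a log2 difference of 5.97. Of 24 monocyte and macrophage genes, 3 rose and 11 fell on both scales and 14 were called lower as deposited. Both directions together, 17 were called, the same 17 when adjusted over the list alone. The monocyte median was -1.497 against -0.95 to -0.16 for its random lists (camera adjusted p = 0.94 with an estimated correlation). The same list differed by a median of 0.37 between the 2 sensitive arrays, above all 10000 of its random lists. Cd14, another monocyte marker, differed by 0.61 and was not called.

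Elane, which encodes neutrophil elastase, rose from 311 ± 54.8 to 11153, a log2 difference of 4.96. The granule gene Lcn2 rose by 6.24 and S100a8, a calcium-binding protein of granulocytes, by 3.22, while Ms4a3, a gene of granulocyte-monocyte progenitors, fell by 2.81. Mpo (80424 ± 5252 against 80905) and Prtn3 (20184 ± 1348 against 20817), 2 further primary granule genes, were not called. Of 24 neutrophil granule and granulocyte genes, 5 rose and 3 fell on both scales, 5 were called lower as deposited, and 10 were called when adjusted over the list alone. The granulocyte median of 0.01 lay above its random range of -0.81 to -0.15, with an adjusted p = 0.94 with an estimated correlation. It was inside that range after quantile normalization, and the list differed by a median of 0.25 between the sensitive arrays (percentile 98.95). The call of Ms4a3 was lost after quantile normalization (-2.26) and with the floor of 50.

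Most interferon genes and several antigen presentation genes fell in the resistant cells. Rtp4 fell from 2963 ± 1664 to 14 units, a log2 difference of -5.44, and the antiviral gene Oas2 fell by 4.71. Usp18, a negative regulator of the interferon receptor, was called lower with a probe near 0 on the resistant array (-4.07, 4.67 units), where a failed spot was not excluded, and Ifi27l2a fell by 3.92. Of 24 interferon response genes, 2 rose and 14 fell on both scales and 19 were called lower as deposited. Both directions together, 21 were called, the same 21 when adjusted over the list alone. The interferon median was -2.10, below all of its 10000 random lists (camera adjusted p = 0.94 with an estimated correlation), but the sensitive arrays themselves differed in this list by a median of 0.72, with replicate 2 higher. Psmb8, a second immunoproteasome subunit gene, fell from 9932 ± 378 to 317, a log2 difference of -4.76. Nlrc5, the transactivator of MHC class I genes, fell by 4.57 and the peptide transporter gene Tap1 changed by -2.997. B2m, the light chain of MHC class I, differed by -0.66 as deposited and 0.10 after scaling and was not called. In the antigen presentation list 6 of 13 genes fell on both scales, 8 as deposited and 8 when adjusted over the list alone. Its median of -1.40 lay below its random range of -1.09 to 0.02, with an adjusted p = 0.94 with an estimated correlation, and its members differed little between the sensitive arrays (median 0.08).

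More inflammatory genes fell than rose. The chemokine gene Ccl2 fell from 3062 ± 2208 to 21.8, a log2 difference of -5.23, with 1501 and 4623 on the sensitive arrays. Nfkbia, the inhibitor and target of NF-kB, fell by 3.61, while the chemokine gene Ccl6 rose by 3.51. The prostaglandin synthase gene Ptgs2 (-3.57) was called lower with -3.11 units on the resistant array, where a failed spot was not excluded. Of 24 genes in this list, 3 rose and 10 fell on both scales, 11 were called lower as deposited, and 14 were called when adjusted over the list alone. The list median of -1.10 lay below the random range of -0.96 to -0.17 (camera adjusted p = 0.96 with an estimated correlation). It was inside the random range without sensitive replicate 2, and it differed between the sensitive arrays by 0.49. In the adhesion and migration list 5 of 20 genes fell, and 5 when adjusted over the list alone, at percentile 59.0 of random lists. They included Cd24a (-3.43), the hyaluronan receptor gene Cd44 (-2.99) and the gut-homing integrin gene Itgb7 (-2.79). The integrin ligand gene Icam1 was called lower (1259 ± 194 against 6.22) on a probe near 0, where a failed spot was not excluded. After quantile normalization Oas2 (-4.12), Usp18 (-3.81), Ccl2 (-4.67) and Ptgs2 (-3.29) differed by at least 1 but lost their calls on the adjusted p, as all but Oas2 did with the floor of 50 and Ccl2 did with a robust trend.

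Several genes of DNA copying and chromatin fell, and others were lower on the deposited scale only. Ccnd1, which encodes cyclin D1, fell from 5587 ± 1126 to 487, a log2 difference of -3.38. The survivin gene Birc5 fell by 1.81, whereas Ccnd3 (-1.90) and the replicative helicase gene Mcm7 (-1.60) were called lower as deposited only and the proliferation marker gene Mki67 differed by -1.10 without a call. In the cell cycle list 10 of 23 genes were called lower as deposited, 10 when adjusted over the list alone and 2 on both scales, with a median at percentile 2.92 of random lists. For DNA replication stress and repair, 1 of 22 genes rose and 6 fell on both scales, 10 were called lower as deposited, and 11 were called when adjusted over the list alone. Those that fell included the polymerase genes Pole (-2.16) and Pold1 (-2.07), the exonuclease gene Exo1 (-1.999) and the crosslink repair gene Fanca (-1.90). The repair median of -1.06 lay just below its random range of -1.03 to -0.15 (adjusted p = 0.94 with an estimated correlation) and inside it in 7 of 11 other settings, among them scaling on bright probes and leaving out sensitive replicate 1. The Polycomb methyltransferase gene Ezh2 fell from 5094 ± 953 to 327 (log2 difference -3.76) and its partner Eed fell by 2.40. Kdm5b, a histone H3K4 demethylase gene, rose from 39.2 ± 7.99 to 2248, and the maintenance methyltransferase gene Dnmt1 (-1.70) was called lower as deposited only. Of 19 genes of DNA methylation and chromatin modification, 1 rose and 2 fell on both scales, 10 were called lower as deposited, and 11 were called when adjusted over the list alone. Their median of -1.12 was below the random range of -1.11 to -0.19 (adjusted p = 0.94 with an estimated correlation) and inside it in 4 of 11 other settings, which were scaling on bright probes, the filter on the dimmest 25% of genes, the floor of 50 and leaving out sensitive replicate 1. In ribosome biogenesis and Myc targets, 6 of 12 were called lower as deposited, 6 when adjusted over the list alone and 2 on both scales, Wdr12 (-2.55) and Nle1 (-1.69), while Rrp9 (-1.504) and Mrto4 (-1.24) were called lower as deposited only. That median lay at percentile 8.70.

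Bcl2, the anti-apoptotic gene of mitochondria, rose from 415 ± 20.8 to 3664 (log2 difference 2.997, SE 0.22, limma adjusted p = 6.86e-07). Its relative Mcl1 differed by 0.22 and was not called. Pro-apoptotic Bcl2l11 (-1.61) and Tnfsf10 (-1.25) and the inhibitor gene Birc3 (-1.39) were called lower as deposited only. In the apoptosis list, 1 of 19 genes rose and 4 were called lower as deposited, 5 when adjusted over the list alone, at percentile 56.8, and after scaling 2 were called higher and 0 lower. Among p53 targets, Zmat3 (3.01) and the growth arrest gene Gadd45a (2.14) rose and the damage-binding gene Ddb2 fell by 2.07, while Sesn1 (-1.89) was called lower as deposited only. Cdkn1a, which encodes p21, differed by 1.31 without a call as deposited and was called higher after scaling (2.06). Mdm2 differed by -0.33 as deposited and 0.41 after scaling. Of 21 p53 targets, 4 rose and 1 fell on both scales, 3 were called lower as deposited, and 7 were called when adjusted over the list alone. The median lay inside its random range as deposited (percentile 96.4) and above it after scaling (percentile 98.5). Egr1, an immediate early transcription factor gene, rose by 3.02, and Dusp2 (-2.69), Etv5 (-2.35) and Jun (-1.98) fell. In the list of MAPK feedback and immediate early genes, 2 of 18 rose and 3 fell on both scales, 4 were called lower as deposited, and 6 were called when adjusted over the list alone. Its median was at percentile 57.8, it differed by 0.42 between the sensitive arrays (percentile 99.99), and after scaling 4 of its genes were called higher and 3 lower. Calls lost on the adjusted p after quantile normalization included those of Pole (-1.57), Pold1 (-1.46), Egr1 (3.56), Etv5 (-1.78) and Jun (-1.39), and the floor of 50 ended those of Gadd45a and Egr1 in the same way.

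Several stem and progenitor genes fell. Sox4 fell from 4847 ± 1066 to 198, a log2 difference of -4.29. The homeobox genes Hoxa7 (-4.01) and Hoxa5 (-2.78) fell, the receptor gene Flt3 (-2.65, and -1.99 after scaling) lost its call after scaling on the adjusted p, and Kit, a further receptor gene of progenitors, differed by -0.01 as deposited and 0.74 after scaling. Of 19 haematopoietic stem and progenitor genes, 1 rose and 5 fell on both scales and 8 were called lower as deposited. Both directions together, 9 were called, the same 9 when adjusted over the list alone. Their median was at percentile 76.4. Quantile normalization ended the call of Hoxa7 on the adjusted p, with a log2 difference of -3.51.

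Several hypoxia-responsive genes rose. Vegfa, the vascular growth factor gene, went from 2433 ± 214 to 19315 (log2 difference 2.97) and Ndrg1 from 2540 ± 93.9 to 19216. The lactate transporter gene Slc16a3 rose by 6.25 and the oxidoreductase gene Ero1a by 3.59, whereas the glucose transporter gene Slc2a1 (0.40) and the hexokinase gene Hk2 (0.33) were not called as deposited, and Hk2 was called higher after scaling (1.09). Of 19 genes of glycolysis and hypoxia, 4 rose and 2 fell on both scales, 3 were called lower as deposited, and 7 were called when adjusted over the list alone. The median of 0.29 lay above the random range of -1.003 to -0.12, with an adjusted p = 0.94 with an estimated correlation. In cholesterol and fatty acid synthesis, the elongase gene Elovl6 rose by 1.33 and the carboxylase gene Acaca fell by 1.83. The squalene epoxidase gene Sqle differed by 0.87 without a call as deposited and was called higher after scaling. Of 14 genes 1 rose and 1 fell, 2 when adjusted over the list alone, and after scaling 5 were called higher and 1 lower. The median of 0.12 lay above its random range of -1.19 to -0.10 (adjusted p = 0.94 with an estimated correlation). Mgst1, a microsomal glutathione transferase gene, was called higher (5.08 ± 1.59 against 3413) on a probe near 0 on both sensitive arrays, where failed spots were not excluded, and the cystine transporter gene Slc7a11 rose by 3.62, while Mgst3 (-3.67) and Gstt1 (-1.96) fell. Of 21 genes of glutathione and oxidative stress, 2 rose and 4 fell on both scales, 5 were called lower as deposited, and 7 were called when adjusted over the list alone, at percentile 49.1. The stress-responsive genes Ddit4 (2.43), Dnajb9 (2.10) and Xbp1 (1.83) rose and Ddit3 fell by 2.03. Of 17 genes of the integrated stress and unfolded protein response, 3 rose and 1 fell on both scales, 2 were called lower as deposited, and 5 were called when adjusted over the list alone, at percentile 74.4. In oxidative phosphorylation Sdhb fell by 2.16, and Uqcrc1 (-1.76), Ndufs1 (-1.60) and Uqcrfs1 (-1.49) were called lower as deposited only. Of its 20 genes 1 rose and 1 fell on both scales, 5 were called lower as deposited, and 6 were called when adjusted over the list alone, at percentile 82.8, while after scaling 4 were called higher and 1 lower. The calls of Elovl6 (1.68), Acaca (-1.23) and Ddit3 (-1.42) were lost after quantile normalization, and those of Elovl6, Ddit3 and Ddit4 with the floor of 50.

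**Figure D3:**
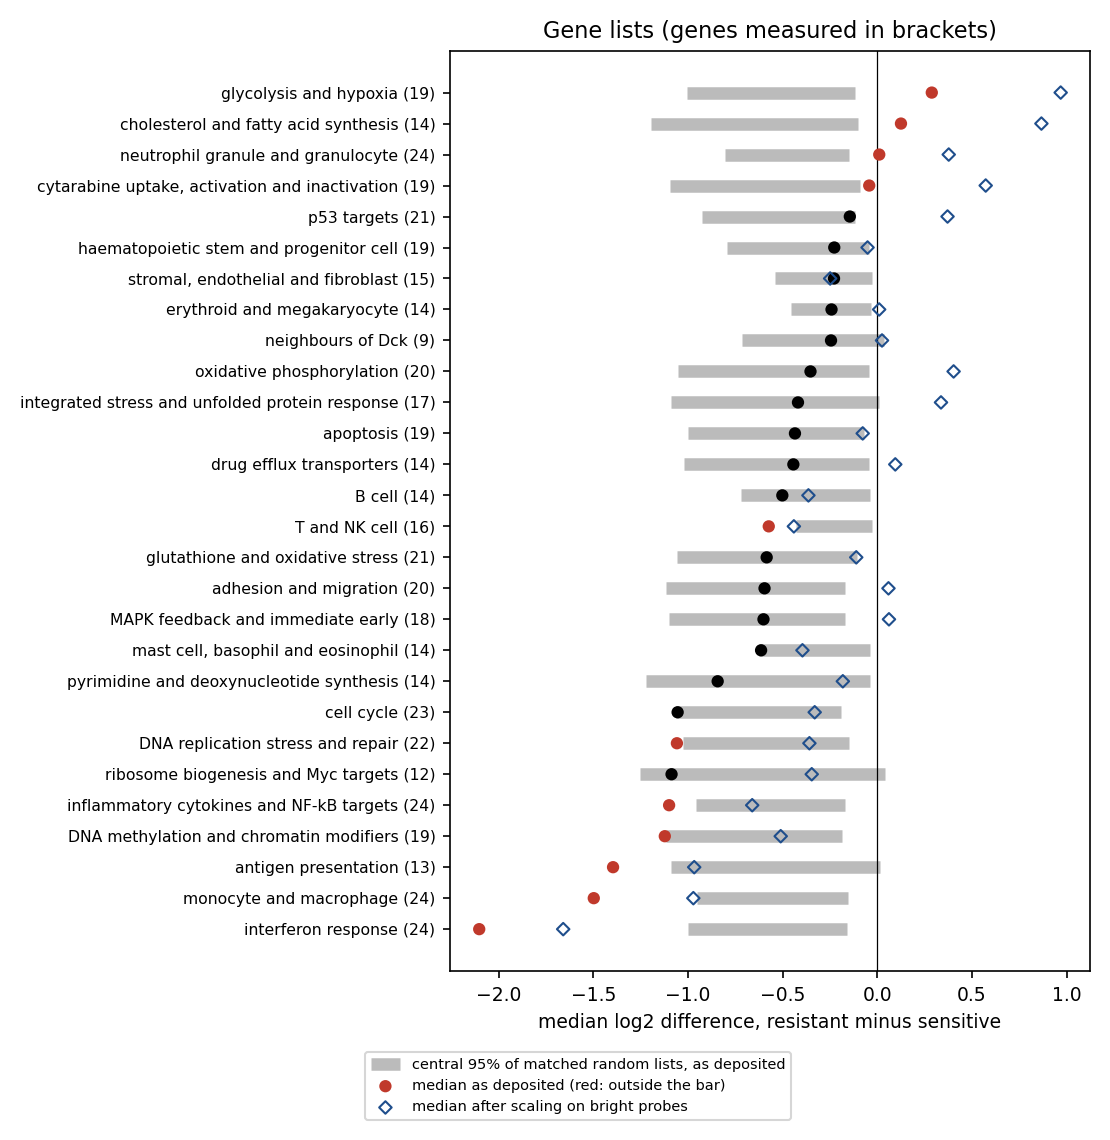
For each of 28 gene lists the filled point gives the median log2 difference between resistant and sensitive cells as deposited, the grey bar the central 95% of 10000 random lists matched on expression, and the open diamond the median after scaling on bright probes. Interferon response (-2.10) and monocyte and macrophage (-1.497) lay farthest below their bars, and glycolysis and hypoxia (0.29) above its bar.

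Markers of other cell types moved in both directions. Of 14 B cell genes, 3 rose and 4 fell on both scales, 5 were called lower as deposited, and 8 were called when adjusted over the list alone. Igll1 rose, while Cd79b (-3.88) and Vpreb1 (-2.98) fell. The adaptor gene Blnk (-3.96) was called lower on a probe that read -6.22 on the resistant array, where a failed spot was not excluded. In the T and NK cell list 3 of 16 genes fell on both scales, 5 as deposited and 5 when adjusted over the list alone. The interleukin receptor gene Il7r fell from 1644 ± 577 to 10.9, and Cd5 (-2.52) and Nkg7 (-2.45) fell too, while Klrd1 (-1.55) was called lower as deposited only. This median of -0.57 lay below its random range of -0.43 to -0.03 (adjusted p = 0.94 with an estimated correlation). Among 14 erythroid and megakaryocyte genes Car2 (1.28) was called higher, at 85.6 units against 3.73 and 7.91 on the sensitive arrays. Vwf (-1.64) was called lower with 7.78 units on the resistant array. Failed spots were not excluded for either gene, and 2 were called when adjusted over the list alone. For mast cells, basophils and eosinophils, 2 of 14 were called lower as deposited only, Prg2 (-1.52, and -1.30 after scaling) and Hdc (-1.35, and -1.11 after scaling), and 2 when adjusted over the list alone. Of 15 stromal, endothelial and fibroblast genes, 3 rose and 2 fell, and 5 were called when adjusted over the list alone. The matrix glycoprotein gene Thbs1 rose from 69.2 ± 6.55 to 6396 and the receptor gene Kdr rose by 2.37, while Pdgfrb fell by 1.94. Fn1 (-2.80) was called lower with 7.78 units on the resistant array, where a failed spot was not excluded. The medians of the B cell, erythroid, mast cell and stromal lists were at percentiles 19.45, 48.7, 2.80 and 60.5. Across the 28 lists, 11 medians lay outside their random range, where 1.40 would if list members varied as independently as randomly drawn genes. That independence was not shown, and 7 lay outside in the comparison of the 2 sensitive arrays with each other. Those 7 include chromatin modifiers (percentile 2.475) and erythroid and megakaryocyte (2.45). By camera 10 lists passed an adjusted p of 0.05 with a preset correlation of 0.01 and 0 with an estimated one. The call of Pdgfrb was lost after quantile normalization (-1.35), and that of Car2 with the floor of 50 and with an offset of 100.

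The sensitive arrays were much closer to each other than to the resistant array. Across genes, which are not independent replicates, Pearson's r was 0.991 between the sensitive arrays and 0.878 and 0.880 between each of them and the resistant array. The SD of the log2 difference was 0.29 between the sensitive arrays and 1.07 and 1.06 against the resistant array. Judged as the lone array, sensitive replicate 1 differed by at least 1 log2 unit from both others in 42 genes, sensitive replicate 2 in 85 and the resistant array in 4205. Where a called gene had another probe of at least 500 units on an array, 137 of 147 such probes differed in the same direction as deposited, against a mean of 95.8 and a highest of 113 when calls and probes were paired at random in 10000 permutations. After scaling on bright probes 109 of 120 did, against a mean of 63.3 and a highest of 83.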

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

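The 6046 probes without a gene name were used in no comparison of named genes or gene lists above, and they too differed between resistant and sensitive cells; both counts were taken after the data were examined. By size alone (at least 1 log2 unit from each sensitive array), 125 of them were higher on the resistant array and 561 lower, while 37 differed by that much between the sensitive arrays. The unnamed probe with the largest rise read 14.9 and 19.8 in sensitive cells and 29843 in resistant cells. What these probes measure is not reported here.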

How the results depend on the processing

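Scaling on bright probes, the offsets of 16 and 100, the floor and the removal of near-zero probes were chosen after the data were examined. The 4205 called genes became 2528 after quantile normalization, 8511 by adjusted p alone and 1084 at a log2 difference of at least 2. The 926 higher genes became 1694 after centring on the medians, 1737 after scaling on bright probes, 1566 by adjusted p alone and 353 at a difference of at least 2. The 3279 lower genes became 1197 after quantile normalization, 1269 after centring, 1512 after scaling on bright probes, 6945 by adjusted p alone and 731 at a difference of at least 2. The thresholds act by construction. Of the 4205 genes, quantile normalization took 1757 below the size rule and 365 more past the adjusted p, with a prior of 1.74 degrees of freedom in place of 11.2, and 445 other genes were newly called. For the other moves the cause was not tested. In every other setting run these counts stayed within 1.5 times, from 2963 (centring) to 5845 (offset of 16) in total. The total was 4166 without the 39 genes whose probe read at least 500 on both sensitive arrays and at most 10 on the resistant array. By size, 4205 genes became 6925 at 0.6 and 1084 at 2, and 4726 to 5256 with 1 sensitive array left out. The lists outside their random range, 11 as reported, were 9 to 11 with 1 sensitive array left out, 9 to 13 over all settings but 1, and 0 by camera with an estimated correlation, which had 1 residual degree of freedom to estimate it from. The Dck difference was 0.14 to 0.20 with 1 sensitive array left out, and over all settings 0.14 to 0.93 without a call, with adjusted p between 0.000446 (centring) and 0.50. The SD between the sensitive arrays ranged from 0.24 (offset of 100) to 0.40 (offset of 16). Leaving out a sensitive array leaves limma no residual degrees of freedom, so calls have no value there. No paired analysis was possible because the resistant group has 1 array.

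Of 128 named genes that were called, 0 changed direction in any setting; 35 lost the call after quantile normalization (18 of them still passing the size rule), 21 after scaling on bright probes (2 still passing it), 19 after centring, 19 with the floor (17 still passing it), 6 with the offset of 100 and 1 with the robust trend. Besides Dck, whose sign held, 16 named genes were not called, and 5 of them changed sign. After quantile normalization the log2 difference was 0.19 for Mdm2, 0.45 for Kit and -0.19 for Mpo. After centring it was 0.041 for Abcc1, 0.29 for Mdm2 and 0.61 for Kit. After scaling on bright probes it was 0.16 for Abcc1, 0.41 for Mdm2, 0.74 for Kit and 0.10 for B2m. The cause was not tested. Signal over background limits dim genes: 43.0% of probes on the resistant array read at least 50 units.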

Other observations

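All tests in this part were chosen after the result was seen, and so were the genes named in it that the report does not name. The sensitive arrays differed from each other by at least 1 log2 unit in 152 genes, 125 of them higher on replicate 2. The chemokine genes Ccl2 (1501 and 4623) and Ccl7 (321 and 1155), the cytokine feedback gene Socs3 (217 and 1043) and the interferon-induced genes Ifitm3 (483 and 1930) and Rnf213 (322 and 1200) were higher on replicate 2. So were the non-coding RNAs Rn7sk (813 and 2550) and Rmrp (242 and 913). Ifitm3 read 33650 on the resistant array, opposite to most genes of the interferon list. The licensing kinase regulator gene Dbf4 read 4030 on replicate 1, 7.91 on replicate 2 and 2831 on the resistant array, and the pentose phosphate enzyme gene Rpia read 1666, 11.9 and 3177.

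Expression after scaling on bright probes also differed by chromosome among genes of at least 500 units on an array. The median log2 difference was -0.51 over 397 genes of chromosome 4, -0.41 over 373 genes of chromosome 1 and -0.26 over 507 genes of chromosome 11, against 0.23 for chromosome 15 and 0.22 for chromosome 3. For chromosomes 1, 4 and 11 the two-sided p against 10000 random draws of as many genes, with replacement, was 0.0002, the smallest it can give (Benjamini-Hochberg adjusted p = 0.0013 over the chromosomes). By the same draws the adjusted p was also under 0.05 for chromosome 7, which was lower, and for chromosomes 3, 9, 10 and 15, which were higher. Genes are not independent replicates, and DNA copy number was not measured here.

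The first pattern weighed is that of probes near 0 on the resistant array only. There were 47 such probes among 6019 bright on both sensitive arrays; between the sensitive arrays the same rule gave 2 and 1. They formed 7 neighbouring pairs in the order of probe numbers, above the highest of 10000 permutations (4). That order need not match places on the slide, whose layout was not used here. The most in any 50 consecutive bright probes, wherever they lay, was 11, against a highest of 7 in 10000 permutations. Failed spots that lay together on the resistant array are a candidate explanation for the 11 probes in pairs, which include Tmem223, Nsmce4a, Get3 and Gimap6. For the 36 probes outside pairs, among them Rsl1d1, Hax1, Icam1, Blnk and Usp18, failed spots and a change of transcript level in the resistant cells cannot be told apart with 1 array. Of these 36, 3 lay among those 50 consecutive probes, Tmem214, Srp72 and an unnamed one. For 4 others the gene had another bright probe. On the resistant array it read 21.8 for Scin, 20.2 for Evl and 31.1 for Ms4a6d, against 2845 and 2875, 1768 and 1531, and 2021 and 2687 on the sensitive arrays. For Srsf1 it read 1380 against 3978 and 3593, a far smaller fall than on the near-zero probe (3.11 against 2992 and 2548). Pacc1, whose near-zero probe was in a pair (-7.78 against 662 and 683), read 451 on another probe, against 2356 and 1855.

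The second pattern is the number of genes called. After scaling that removed the median shift of bright probes 3249 genes were called. Of these, 2417 were among the 4205 as deposited and in the same direction, and 832 were newly called. This argues against 1 factor per array as the whole cause, though the scaling moved the balance of directions. Among 5318 bright genes the median difference as deposited ran from -0.87 in the dimmest 1064 to -0.56 in the brightest 1064. Scaling by 1 factor therefore did not remove the dimness at every level. Quantile normalization, which gives the arrays the same distribution, left 2083 of the 4205 called in the same direction. Probes of at least 500 on both sensitive arrays and at most 10 on the resistant array accounted for 39 of the 4205 called genes. Failed spots of such bright genes are too few to be the cause. Dimmer genes such as Fn1 (354 ± 32.1 against 7.78) and readings just above 10 such as Il7r (10.9) escape this rule, so failed spots beyond it were not counted. Whether the array came from cells of another origin than the parental line cannot be told apart from a change under cytarabine selection: the correlation with sensitive replicate 1 across genes was 0.878, and the resistant group has no further array. The design's own difference, resistance, stays open and untested for the same reason.

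The third pattern is that of 38 probes at or below 10 on both sensitive arrays and at least 500 on the resistant array, such as those of Col9a1, Serpine2, Pmp22 and Ppib. Stromal cells in the resistant sample would bring collagen and matrix transcripts, yet the highest of 6 abundant ones (Col1a1, Col1a2, Col3a1, Sparc, Dcn and Lum) read 15.6 on the resistant array, which argues against cells rich in these 6. They read at most 41.0 on the sensitive arrays, so no array here shows that their probes respond. Of the 15 genes in the stromal list 3 were called higher, among them Thbs1 and Kdr, and 2 lower. Failed spots on both sensitive arrays could account for some of these probes: 2 neighbouring pairs were found against a permuted mean of 0.281 (permutation p = 0.031, highest 3), so the 2 explanations, failed spots and a rise in the resistant cells, cannot be told apart for the set. Igf1 was in the set on 2 separate probes, which read 0 and 3.96 against 882, and 6.21 and 0 against 541. Further probes of the other genes were not weighed here. Ppib is of interest here, since a widely expressed gene read below 0 on both sensitive arrays.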
